A study of Homo sapiens with 36 samples.

How the data were processed

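The series measured total RNA of human primary differentiated adipocytes on 36 Human Clariom S arrays with biotin-labelled targets, per the labels' protocols. Cells received vehicle, 100 nM GIP, 100 nM insulin or both for 2, 8 or 24 h, with 3 samples in each of 12 groups. Groups, times, doses and replicate numbers were taken from the sample labels. The deposited table holds log2 expression values, one column per array. Per the submitters' processing notes the arrays were summarised by RMA, a method that corrects background and combines the probes of a probe set, with no version given, and per the series' design text the values were quantile-normalized. Quantile normalization makes the distributions of the arrays alike, so a change of total RNA output per cell cannot be seen. RMA can compress fold changes of dim genes. As its version is not given, how it scaled fold changes here is not known. The genome build is not given in the sources used here. The labels' extraction text speaks of frozen tissue, while the sample labels name cultured adipocytes. No detection calls were used, so a dim probe set was not separated from background, except in the alternative that leaves out dim rows.

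The table has 24351 rows. Of these, 2903 are control rows, which were left out, as were 77 gene rows on the Y chromosome or for XIST or TSIX. The 21371 rows left were tested. Through the platform annotation, 17682 of them pair with 1 gene symbol, 0 with several and 3689 with none, and 17682 symbols were matched by gene ID to the RefSeq gene table, which changed 0 of them. Where several rows shared a symbol (19 extra rows), the row with the highest mean stands for the gene. CREM is not analysed here. Column medians ranged from 5.986 to 6.058 and values from 1.51 to 19.85. Within groups, the difference of 2 replicate arrays had an SD from 0.338 to 0.426 over 36 pairs, and 0 pairs of columns were identical. No depth applies to arrays, and their number limits the precision.

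No further normalization was applied. Differences between groups were fitted with limma 3.58.1 in R 4.3.3: a linear model with 1 mean per group over all 36 arrays (24 residual and 7.19 prior degrees of freedom), moderated by eBayes, two-sided, with Benjamini-Hochberg adjustment over the 21371 rows within each comparison and a threshold of 0.05. GIP, insulin and both were compared with vehicle, and insulin plus GIP with insulin, at each time. Differences of effects (with and without insulin, and 24 h against 2 h) and vehicle at 24 h against 2 h came from the same fit. The design of each test, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The genes named were, among rows with 1 symbol, a higher group mean of at least the table median of 6.022, a passed threshold and no overlap of the 3 arrays of both groups, the 5 largest rises and falls in GIP vs vehicle, insulin vs vehicle and insulin plus GIP vs insulin and the 3 largest in the other comparisons, up to 4 members of each list with the smallest p, and a short set of receptor, hormone and metabolic genes given with their values.

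Tests over groups of genes used 24 lists: cAMP-responsive genes, MAPK early and feedback genes, lipolysis and lipid droplet, de novo lipogenesis, fatty acid uptake and triglyceride synthesis, cholesterol synthesis, glucose uptake and glycolysis, FOXO target genes, branched-chain amino acid catabolism, oxidative phosphorylation, fatty acid oxidation, thermogenic adipocyte, mature adipocyte, adipose progenitor and fibroblast, endothelial, macrophage, mural and smooth muscle, inflammatory cytokines and NF-kB, interferon-stimulated genes, unfolded protein response, amino acid response and ATF4 targets, ribosome biogenesis, circadian clock and cell cycle. Some genes stand in several lists. Lists were tested with limma's camera (preset correlation 0.01) in 9 comparisons, with Benjamini-Hochberg adjustment over the 24 lists. With an estimated correlation the calls that held numbered 1 of 6, 7 of 10 and 6 of 11 for GIP at 2, 8 and 24 h, 7 of 10, 8 of 11 and 10 of 11 for insulin, and 1 of 6, 5 of 10 and 2 of 7 for GIP in the presence of insulin. Calls shared by GIP and insulin, which use the same vehicle arrays, were set beside 100 simulations of unchanged groups.

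The fit was tested on simulated data for GIP vs vehicle at 2 h over 21371 rows. It recovered 20 of 100 genes changed 1.5-fold and 73 of 100 changed 2-fold, with 6 false calls among 99. In 20 simulations the shifted list was called 20 times, and 1 of 460 other list tests was called. The simulated genes varied independently of each other. Members of a real list may vary together, so this is not the rate of false list calls in the real data. The alternatives tried were cyclic loess, median centring, leaving out dim rows (highest group mean under the table median), only the groups compared, the replicate number as a block over all times or within each time, a trended robust fit, array weights, an added 1.5-fold minimum, plain ANOVA by the submitters' rule (unadjusted p under 0.05 and 1.5-fold) and after adjustment, 1 row per gene, and leaving out each array in turn. For lists they were camera with an estimated correlation, fry, the replicate block, leaving out dim rows and each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.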

Results

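Gene expression was measured in human primary differentiated adipocytes, fat cells made in culture from precursor cells, after vehicle, 100 nM GIP, 100 nM insulin or both hormones together. GIP, the glucose-dependent insulinotropic polypeptide, is a gut hormone released after a meal whose receptor raises cAMP. Insulin is the pancreatic hormone that drives glucose uptake and fat storage in adipocytes. Each of the 4 treatments was sampled at 2, 8 and 24 h with 3 replicates, giving 12 groups and 36 Clariom S arrays. The 36 arrays had median log2 values from 5.99 to 6.06, and the number of arrays per group limits the precision. The labels do not say whether replicates were separate cultures or donors, so p-values measure only the spread between these samples, which may be technical. Log2 changes are given ± SE and levels ± SD, with n = 3 arrays in each group. A gene is said to have risen or fallen where limma's adjusted p was under 0.05 over 21371 probe sets. Unless times are compared, this is against the control group at the same time, and the series holds no sample from before treatment. Counts of genes called in a comparison are counts of probe sets, and 3689 of the probe sets tested have no gene symbol. The SE rests on a spread per gene shared by all 12 groups. It is too small for a group whose arrays scatter more than the others. In comparisons of 2 groups, genes named for the largest changes were chosen among those with all 3 arrays of one group above all 3 of the other. Signal was not compared with background, so the size of a fold from a mean under the table median of 6.02 is uncertain. For gene lists, the number of members that passed with each of the 6 arrays left out in turn is given where it moved by more than 1.5 times, and the highest camera adjusted p where the call ended.

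In vehicle at 2 h, ADIPOQ, which encodes the adipocyte hormone adiponectin, had a log2 level of 16.73 ± 0.13, PLIN1, a coat protein of lipid droplets, had 14.75 ± 0.27, and PPARG, the transcription factor that drives adipocyte differentiation, had 13.83 ± 0.09. The GIP receptor gene GIPR had 4.85 ± 0.23 and the insulin receptor gene INSR had 8.45 ± 0.20. GLP1R and GCGR, the receptors of related hormones, had 4.68 ± 0.24 and 2.64 ± 0.15. Probe sets differ in affinity, so these levels do not rank the genes against each other. GIPR was lower in vehicle at 24 h than at 2 h by a log2 change of -1.97 ± 0.21. Its levels at 2 h and 24 h (2.88 ± 0.05) both lay under the table median, so the size of this change is uncertain.

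**Figure D1:**
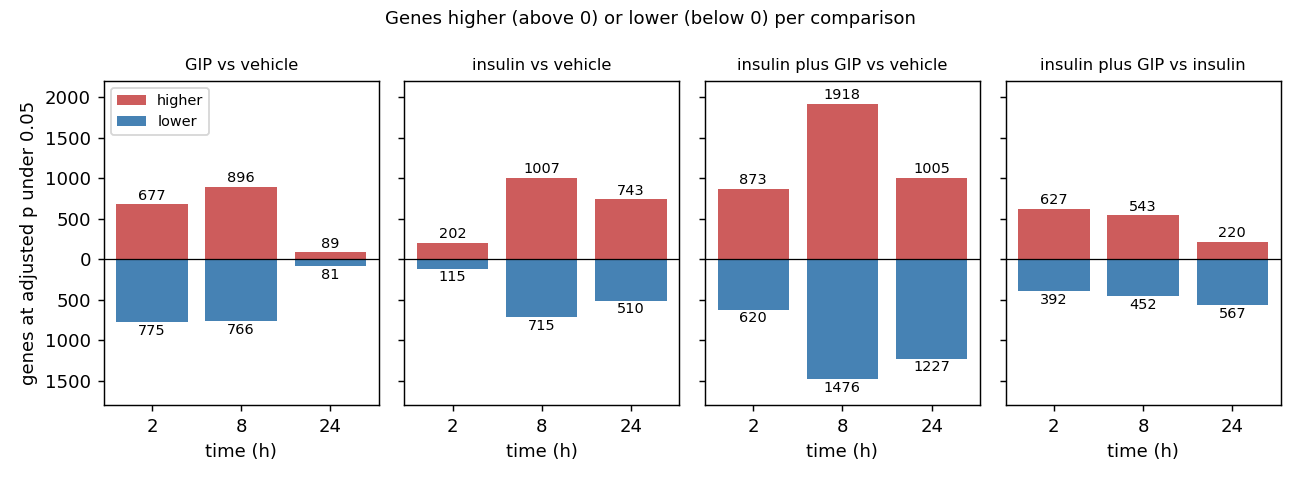
Number of probe sets, called genes here, past the threshold (y axis, adjusted p under 0.05) that were higher (red, above 0) or lower (blue, below 0) in each comparison at 2, 8 and 24 h (x axis). GIP alone called 1452, 1662 and 170 genes at the 3 times, and insulin alone called 317, 1722 and 1253.

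The effect of GIP alone was first compared with vehicle at 2 h. ADAMTS4, a protease of the extracellular matrix, rose 137-fold (log2 change 7.10 ± 0.19), and the nuclear receptor gene NR4A2 rose 126-fold (6.98 ± 0.31). ZNF331, CTH, which encodes the cysteine-forming enzyme cystathionine gamma-lyase, and the deubiquitinase gene USP2 rose by 6.44, 6.13 and 5.82 on the log2 scale. The vehicle mean of CTH, 5.82 ± 0.12, lay under the table median, so the size of its rise is uncertain. DEPP1 had the largest fall, 15.4-fold (-3.95 ± 0.19), followed by EGR1, an immediate-early transcription factor, at -3.06 ± 0.22. EGR1 stood at 9.57 with GIP and 12.64 in vehicle at 2 h, both above the 7.11 of vehicle at 24 h. Its level before treatment is not known. ZNF217, CCN1 and KLF6 changed by -2.82, -2.56 and -2.49. In all, 677 genes were higher and 775 lower, of which 590 and 669 stand for a gene with a symbol. Among cAMP-responsive genes, 14 of 20 measured members rose and 2 fell (16 and 2 adjusted over the list alone, camera adjusted p = 6.2e-44), and their median log2 change was 2.51. RGS2, a brake on G-protein signalling, rose by 4.94, PDE4D, a cAMP phosphodiesterase, by 3.88, NR4A3 by 4.39, and PCK1, the enzyme of glyceroneogenesis, by 3.51. PPARGC1A, a coactivator of mitochondrial genes, rose by 2.88.

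At 2 h of GIP the MAPK, FOXO and inflammatory lists held calls in both directions. Among MAPK early and feedback genes, 5 of 17 measured members rose and 7 fell (6 and 7 adjusted over the list alone, camera adjusted p = 0.76), with HBEGF at 4.56 ± 0.26 and DUSP4 at 3.28 ± 0.14 against EGR1. Their median was below 0 while their mean and test pointed upwards. Among FOXO target genes, 6 of 24 measured members rose and 9 fell (7 and 10 adjusted over the list alone, camera adjusted p = 0.76). PDK4, which shifts cells from glucose to fat oxidation, rose by 2.53, while TXNIP and TRIB1 changed by -2.13 and -2.18. Among amino acid response and ATF4 targets, 3 of 19 measured members rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 4.11e-06, adjusted p = 0.0553 with an estimated correlation). The amino acid transporter gene SLC7A5 rose by 5.66 and DDIT4 by 2.92. Among inflammatory cytokine and NF-kB genes, 5 of 20 measured members rose and 2 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.00217, adjusted p = 0.0553 with an estimated correlation). IL6 was higher by 4.58, IL1B by 1.81, and the chemokine gene CCL2 changed by -1.70. Among branched-chain amino acid catabolism genes, 2 of 20 measured members fell and 0 rose (6 and 0 adjusted over the list alone, camera adjusted p = 0.00217, adjusted p = 0.0553 with an estimated correlation, with 1 array out 1 to 4 passed). Among de novo lipogenesis genes 0 of 16 measured members passed the test (0 adjusted over the list alone, camera adjusted p = 0.0236, adjusted p = 0.397 with an estimated correlation, with 1 array out 0 to 1 passed and camera adjusted p = 0.136 at most). Among macrophage markers, 2 of 14 measured members rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.0236, adjusted p = 0.0553 with an estimated correlation, with 1 array out camera adjusted p = 0.103 at most). FCER1G, the shared gamma chain of Fc receptors, rose by 5.69 and CD14 by 1.09, while TYROBP, another marker of the list, had 0.42 ± 0.20 and did not pass (adjusted p = 0.247). Under cyclic loess scaling, 797 genes were higher and 502 lower, so the larger side changes with the scaling. Fitted on the 6 arrays of this comparison alone, 795 genes passed.

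After 8 h of GIP, LYPD3, FCER1G and the ammonium transporter gene RHCG rose 25.9-fold, 25.5-fold and 25.0-fold (log2 changes 4.70 ± 0.33, 4.68 ± 0.32 and 4.64 ± 0.28). Their vehicle means of 3.71, 4.36 and 4.15 were not shown to be above background, so these folds are uncertain. CMSS1 and the tubulin gene TUBA4A rose by 4.56 and 4.46. SREBF1, which encodes a transcription factor of lipid synthesis, fell 7.76-fold (-2.96 ± 0.15), and THRSP, a lipogenesis gene, fell 4.55-fold (-2.19 ± 0.17). CCL2, the cholesterol exporter gene ABCG1 and the matrix protease gene MMP3 changed by -2.93, -2.65 and -2.51. In all, 896 genes were higher and 766 lower. The 6-array fit of this comparison alone called 780.

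Genes of fat handling and of mitochondria made up several of the groups that moved at 8 h. Among mature adipocyte genes, 11 of 20 measured members rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 3.56e-12). LPL, the lipase that takes up fatty acids from lipoproteins, rose by 2.59 ± 0.16, GPD1 by 1.46 ± 0.16, and ADIPOQ by 1.00 ± 0.16, while GPAM changed by -0.98 ± 0.13. Among fatty acid uptake and triglyceride synthesis genes, 5 of 16 measured members rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.000128), FABP5 being higher by 2.06. Among lipolysis and lipid droplet genes, 7 of 20 measured members rose and 1 fell (9 and 4 adjusted over the list alone, camera adjusted p = 0.00186, with 1 array out 4 to 8 passed). PDE3B, the phosphodiesterase through which insulin restrains lipolysis, rose by 1.53 ± 0.16, hormone-sensitive lipase LIPE by 1.05 ± 0.14 and PNPLA2 by 0.93 ± 0.15. Among oxidative phosphorylation genes, 12 of 23 measured members rose and 0 fell (17 and 0 adjusted over the list alone, camera adjusted p = 2.18e-14), led by CYCS, COX5A and CYC1 at 2.08, 0.81 and 0.96. Among fatty acid oxidation genes, 10 of 19 measured members rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 2.83e-09, with 1 array out 4 to 8 passed), with ACAA2 at 1.69 ± 0.12. Among thermogenic adipocyte genes, 4 of 19 measured members rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.00405). UCP1, the uncoupling protein of brown fat, rose from 3.27 ± 0.30 to 5.65 ± 0.96, and KCNK3 rose by 1.91. Both UCP1 levels lay under the table median, so the size of its rise is uncertain. Among de novo lipogenesis genes, 4 of 16 measured members rose and 3 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.104). ACLY and ACACB rose by 1.05 and 1.15 while SREBF1 and THRSP fell. Among cAMP-responsive genes, 6 of 20 measured members rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.00183, adjusted p = 0.0553 with an estimated correlation, with 1 array out 4 to 7 passed), with CRISPLD2 at 2.46. Among glucose uptake and glycolysis genes, 3 of 19 measured members rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.00361, adjusted p = 0.183 with an estimated correlation), with GPI at 0.84 and HK2 at -1.20. Among branched-chain amino acid catabolism genes 3 of 20 measured members rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.0137, adjusted p = 0.0936 with an estimated correlation, with 1 array out 1 to 3 passed and camera adjusted p = 0.135 at most), with BCKDHB at 0.99. Adipose progenitor and fibroblast markers were the list that moved down, where 1 of 17 measured members rose and 6 fell (1 and 8 adjusted over the list alone, camera adjusted p = 5.65e-05), with POSTN, a matrix protein, at -1.93 ± 0.30 and CTHRC1 at -0.84 ± 0.16.

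At 24 h the GIP effect covered fewer genes, 89 higher and 81 lower. PRL, which encodes the hormone prolactin, rose 12.5-fold (3.64 ± 0.22, adjusted p = 1e-12), and the carbonic anhydrase genes CA3 and CA2 rose 7.03-fold and 6.48-fold (2.81 ± 0.19 and 2.70 ± 0.34). FGL2 and the lipase-related AADAC rose by 2.36 and 2.03. CLCA2, PSG4, SPX, MATN2 and PNLIPRP3 fell, with log2 changes of -1.57 ± 0.22, -1.45 ± 0.22, -1.41 ± 0.22, -1.35 ± 0.19 and -1.31 ± 0.22. PCK1 rose by 1.62. Among fatty acid uptake and triglyceride synthesis genes, 2 of 16 measured members rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 8.02e-06, with 1 array out 1 to 2 passed), with FABP5 at 1.41 ± 0.22. Among glycolysis genes 2 of 19 measured members rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 1.73e-06, with 1 array out 0 to 1 passed). Among oxidative phosphorylation genes 1 of 23 measured members rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 2.86e-07, with 1 array out 0 to 1 passed). Among fatty acid oxidation genes 2 of 19 measured members rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 1.73e-06, with 1 array out 0 to 2 passed). Among mature adipocyte genes, 2 of 20 measured members rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.0106, adjusted p = 0.207 with an estimated correlation, with 1 array out 1 to 2 passed and camera adjusted p = 0.0675 at most). Among de novo lipogenesis genes, 2 of 16 measured members fell and 0 rose (4 and 0 adjusted over the list alone, camera adjusted p = 8.34e-05, adjusted p = 0.105 with an estimated correlation, with 1 array out 0 to 1 passed). Among cholesterol synthesis genes 0 of 20 measured members passed the test (3 adjusted over the list alone, camera adjusted p = 0.0443, adjusted p = 0.42 with an estimated correlation, with 1 array out camera adjusted p = 0.24 at most). Inflammatory cytokine and NF-kB genes stood lower as a list, although 0 of 20 measured members passed the test (2 adjusted over the list alone, camera adjusted p = 0.0402, adjusted p = 0.166 with an estimated correlation, with 1 array out camera adjusted p = 0.246 at most).

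Among adipose progenitor and fibroblast markers at 24 h of GIP, 3 of 17 measured members fell and 0 rose (6 and 0 adjusted over the list alone, camera adjusted p = 1.73e-06, with 1 array out 1 to 2 passed), with TAGLN at -0.78 ± 0.13 and POSTN at -1.25 ± 0.30. Among mural and smooth muscle markers, 1 of 8 measured members fell and 0 rose (1 and 0 adjusted over the list alone, camera adjusted p = 0.0443, adjusted p = 0.0826 with an estimated correlation, with 1 array out camera adjusted p = 0.148 at most). That member was ACTA2, smooth muscle actin, at -1.07 ± 0.14. The call of POSTN ended without any 1 of the 3 GIP arrays or of vehicle replicates 1 and 2, with adjusted p from 0.0422 to 0.215 over the 6 arrays left out in turn. The count of 170 genes became 104, 107 or 93 without GIP replicate 1, 2 or 3, 98 or 108 without vehicle replicate 2 or 3, but 285 without dim probe sets, 287 with a trended robust fit and 257 with array weights. It was 39 on the 6 arrays alone, where MATN2, POSTN, TAGLN and ACTA2 did not pass. For lists, 7 were called without GIP replicate 1 against 11 with it.

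Insulin alone gave at 2 h a smaller set, 202 genes higher and 115 lower. PDK4 fell 14.0-fold (log2 change -3.81 ± 0.14, adjusted p = 1.4e-18) and DEPP1 fell 11.4-fold (-3.52 ± 0.19). ARRDC3, HMGB2 and CITED2 changed by -2.69, -2.16 and -1.88. SPRY4, a feedback inhibitor of MAPK signalling, rose 5.93-fold (2.57 ± 0.20), SNAI1 rose 5.41-fold (2.44 ± 0.25), and MIDN, PCK1 and the clock-related repressor BHLHE40 rose by 2.22, 1.94 and 1.93. Among FOXO target genes, 1 of 24 measured members rose and 9 fell (1 and 13 adjusted over the list alone, camera adjusted p = 1.59e-17), PDK4 and CDKN1B among them, while PCK1 was the member that rose. Among MAPK early and feedback genes, 9 of 17 measured members rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 3.1e-25), with DUSP4, DUSP6 and MYC at 1.93, 1.85 and 1.26. Among inflammatory cytokine and NF-kB genes, 4 of 20 measured members rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.000226, with 1 array out 2 to 3 passed), with NFKBIA at 1.14. Among ribosome biogenesis genes, 2 of 19 measured members rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 1.3e-05, with 1 array out 1 to 2 passed). Among cholesterol synthesis genes 2 of 20 measured members rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.000226, adjusted p = 0.121 with an estimated correlation, with 1 array out 0 to 1 passed). Among fatty acid uptake and triglyceride synthesis genes 1 of 16 measured members rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.0159, adjusted p = 0.143 with an estimated correlation, with 1 array out 0 to 1 passed and camera adjusted p = 0.137 at most). Among amino acid response and ATF4 targets 2 of 19 measured members rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.00111, adjusted p = 0.145 with an estimated correlation, with 1 array out 0 to 2 passed). Among mural and smooth muscle markers, 1 of 8 measured members fell and 0 rose (1 and 0 adjusted over the list alone, camera adjusted p = 0.0203, with 1 array out camera adjusted p = 0.0741 at most), the member being the potassium channel gene KCNJ8 at -1.05. The count of 317 became 209 or 204 without vehicle replicate 1 or 2, and 127 on the 6 arrays alone.

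By 8 h insulin had changed 1007 genes upwards and 715 downwards. SLCO4C1, an organic anion transporter, rose 29.3-fold (4.87 ± 0.33), MVD, an enzyme of the mevalonate pathway, rose 15.4-fold (3.95 ± 0.17), and the fatty acid elongase gene ELOVL6 rose 14.3-fold (3.83 ± 0.23). ITIH1 and SLC2A6 rose by 3.38 and 3.02. TMEM37, YPEL3, PDK4, FAXDC2 and the iron exporter gene SLC40A1 changed by -3.57, -3.15, -2.92, -2.71 and -2.55. Among cholesterol synthesis genes, 18 of 20 measured members rose and 1 fell (18 and 1 adjusted over the list alone, camera adjusted p = 1.33e-43), and their median log2 change was 1.47, with HMGCS1, IDI1 and ACAT2 at 2.69, 2.52 and 2.44. Among de novo lipogenesis genes, 12 of 16 measured members rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 1.06e-17), with ACSS2 and ACLY at 1.87 and 1.77. FASN, fatty acid synthase, had a log2 change of -0.03 ± 0.12, which did not pass. Among fatty acid uptake and triglyceride synthesis genes, 8 of 16 measured members rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 8.47e-07, with 1 array out 5 to 8 passed), with DGAT2, which completes triglyceride synthesis, at 1.46. Among FOXO target genes, 1 of 24 measured members rose and 14 fell (1 and 17 adjusted over the list alone, camera adjusted p = 4.93e-19), with GABARAPL1 at -2.22 and IRS2, a substrate of the insulin receptor, at -1.67. INSR itself fell by 1.43 on the log2 scale.

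Among ribosome biogenesis genes at 8 h of insulin, 8 of 19 measured members rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 1.44e-07, with 1 array out 3 to 7 passed), with POLR1A at 0.88. Among amino acid response and ATF4 targets, 11 of 19 measured members rose and 2 fell (11 and 2 adjusted over the list alone, camera adjusted p = 3.29e-05, adjusted p = 0.0691 with an estimated correlation, with 1 array out 8 to 13 passed), with SLC7A11 and TRIB3 at 1.62 and 1.32. Among MAPK early and feedback genes, 6 of 17 measured members rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 1.53e-06). Among glucose uptake and glycolysis genes, 6 of 19 measured members rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.00568, adjusted p = 0.219 with an estimated correlation, with 1 array out 4 to 6 passed). HK1 and SLC2A4, the insulin-responsive glucose transporter GLUT4, rose by 1.26 and 0.95. Among lipolysis and lipid droplet genes, 2 of 20 measured members rose and 6 fell (3 and 8 adjusted over the list alone, camera adjusted p = 0.0344, adjusted p = 0.149 with an estimated correlation, with 1 array out camera adjusted p = 0.138 at most), with LIPE and PLIN1 at -0.95 and -0.84. Among branched-chain amino acid catabolism genes, 6 of 20 measured members fell and 0 rose (9 and 0 adjusted over the list alone, camera adjusted p = 0.000322), with MCCC1 at -1.02. PPARGC1A and CEBPA, an adipocyte transcription factor, changed by -2.03 and -2.13. On the 6 arrays of this comparison alone, 906 genes passed.

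At 24 h of insulin, 743 genes were higher and 510 lower. ELOVL6 rose 16.2-fold (4.02 ± 0.23), the fatty acid binding protein gene FABP3 14.7-fold (3.88 ± 0.26) and MVD 11.7-fold (3.55 ± 0.17). ITIH1 and the fructose transporter gene SLC2A5 rose by 3.19 and 3.19. PLA2G2A, a secreted phospholipase, fell 21.9-fold (-4.45 ± 0.26), and the complement gene C6, ACVR1C, GPX3 and haptoglobin HP changed by -2.46, -2.16, -2.15 and -2.11. In vehicle PLA2G2A rose from 10.60 at 2 h to 14.57 at 24 h, and with insulin at 24 h it stood at 10.12. Among cholesterol synthesis genes, 15 of 20 measured members rose and 1 fell (17 and 1 adjusted over the list alone, camera adjusted p = 4.6e-35). Among de novo lipogenesis genes 8 of 16 measured members rose and 1 fell (11 and 3 adjusted over the list alone, camera adjusted p = 1.2e-11). Among glucose uptake and glycolysis genes 9 of 19 measured members rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 1.6e-11), with SLC2A3 at 1.70. Among mature adipocyte genes, 7 of 20 measured members fell and 0 rose (10 and 1 adjusted over the list alone, camera adjusted p = 2.78e-11). ADIPOQ changed by -1.82 ± 0.16, AQP7, the glycerol channel, by -1.34 ± 0.14, LPL by -1.28 ± 0.16 and PLIN1 by -1.19 ± 0.16. Among lipolysis and lipid droplet genes, 1 of 20 measured members rose and 7 fell (3 and 9 adjusted over the list alone, camera adjusted p = 8.49e-05), with PDE3B at -1.02. Among FOXO target genes, 1 of 24 measured members rose and 9 fell (1 and 14 adjusted over the list alone, camera adjusted p = 4.92e-10, with 1 array out 6 to 9 passed). Among branched-chain amino acid catabolism genes, 5 of 20 measured members fell and 0 rose (6 and 0 adjusted over the list alone, camera adjusted p = 3.85e-05, with 1 array out 2 to 4 passed), with MCCC1 and ALDH6A1 at -1.47 and -1.07. Among MAPK early and feedback genes 3 of 17 measured members rose and 0 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.000417). In the amino acid response and ATF4 list 4 of 19 measured members rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.000287, adjusted p = 0.0971 with an estimated correlation, with 1 array out 3 to 6 passed). Among cell cycle genes 3 of 20 measured members rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 4.24e-05, with 1 array out 1 to 4 passed). On the 6 arrays alone, 674 genes passed.

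**Figure D2:**
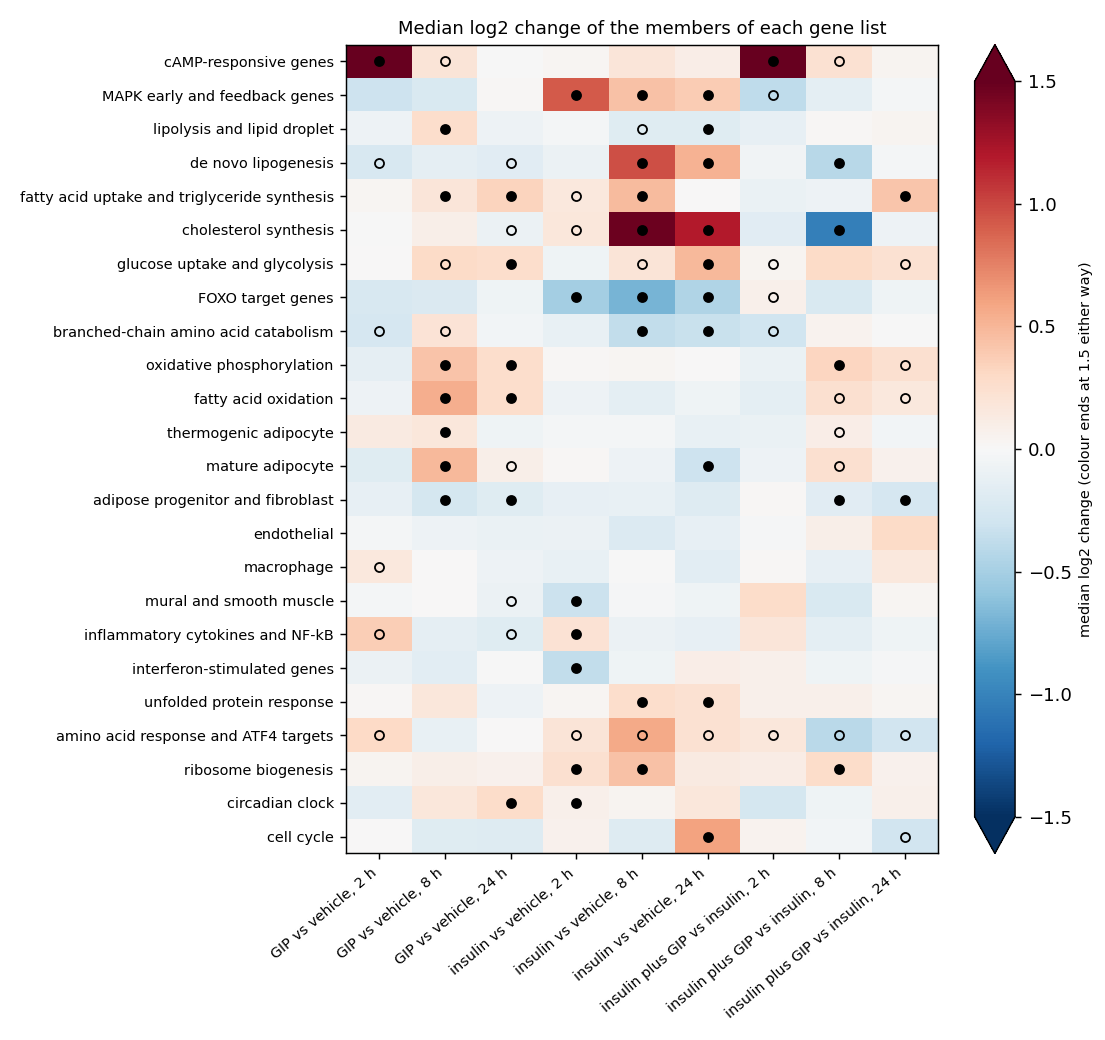
Median log2 change (colour, red higher and blue lower) of the measured members of each of 24 gene lists (rows) in 9 comparisons (columns). Circles mark lists with a camera adjusted p under 0.05, filled where the call held with an estimated correlation; the cAMP-responsive list had medians of 2.51 and 2.27 for GIP at 2 h without and with insulin, and cholesterol synthesis had 1.47 and 1.19 for insulin at 8 and 24 h.

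The effect of GIP in the presence of insulin was read from insulin plus GIP against insulin alone. At 2 h NR4A2 rose 230-fold (7.85 ± 0.31), ZNF331 168-fold (7.39 ± 0.25) and ADAMTS4 90.8-fold (6.51 ± 0.19), and CTH and USP2 rose by 6.45 and 5.99. The insulin means of NR4A2 (5.98 ± 1.15) and CTH (5.20 ± 0.16) lay under the table median, so the sizes of their rises are uncertain. DUSP6, a phosphatase that shuts off ERK, fell 11.3-fold (-3.51 ± 0.17), and MSC, ZNF217, EGR3 and CCL2 changed by -2.58, -2.37, -2.32 and -2.28. In all, 627 genes were higher and 392 lower. Among cAMP-responsive genes, 14 of 20 measured members rose and 0 fell (16 and 0 adjusted over the list alone, camera adjusted p = 1.06e-54). Among MAPK early and feedback genes, 4 of 17 measured members rose and 8 fell (4 and 9 adjusted over the list alone, camera adjusted p = 0.00702, adjusted p = 0.0977 with an estimated correlation). HBEGF and PHLDA1 rose by 3.47 and 2.38. Among FOXO target genes, 6 of 24 measured members rose and 3 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.0417, adjusted p = 0.162 with an estimated correlation, with 1 array out camera adjusted p = 0.128 at most). PDK4 rose by 5.08 ± 0.14 and the pro-apoptotic BCL2L11 by 2.96 ± 0.24, and TXNIP changed by -1.79 ± 0.16. Among amino acid response and ATF4 targets 4 of 19 measured members rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 4.4e-05, adjusted p = 0.0977 with an estimated correlation). Among glucose uptake and glycolysis genes 3 of 19 measured members rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.0417, adjusted p = 0.288 with an estimated correlation, with 1 array out 1 to 3 passed and camera adjusted p = 0.256 at most). Among branched-chain amino acid catabolism genes 1 of 20 measured members fell and 0 rose (1 and 0 adjusted over the list alone, camera adjusted p = 0.00129, adjusted p = 0.0664 with an estimated correlation, with 1 array out 0 to 1 passed). On the 6 arrays alone, 636 genes passed.

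At 8 h with insulin present, GIP raised DPYSL3 24.5-fold (4.62 ± 0.23), FCER1G 23.1-fold (4.53 ± 0.32) and LYPD3 16.9-fold (4.08 ± 0.33), and TUBA4A and MLLT11 rose by 4.02 and 3.73. The insulin means of DPYSL3, FCER1G and LYPD3 were 5.07, 4.18 and 3.51, so their folds are uncertain in the same way. SLCO4C1 fell 27.6-fold (-4.79 ± 0.33), ITIH1 9.15-fold (-3.19 ± 0.22) and ELOVL6 5.15-fold (-2.36 ± 0.23), and ITGA3 and TM4SF19 changed by -2.22 and -2.13. Among cholesterol synthesis genes, 14 of 20 measured members fell and 0 rose (17 and 0 adjusted over the list alone, camera adjusted p = 6.62e-26), with a median log2 change of -1.03 and MVD at -1.89. HMGCS1 and SC5D each fell 2.83-fold. Among de novo lipogenesis genes, 1 of 16 measured members rose and 8 fell (1 and 10 adjusted over the list alone, camera adjusted p = 1.47e-11), with THRSP and SREBF1 at -1.55 and -0.97, and ACSS2 fell 2.83-fold. Against vehicle, MVD in insulin plus GIP at 8 h stood at 11.85 ± 0.17 compared with 9.80 ± 0.31 in vehicle and 13.75 ± 0.12 in insulin. Among amino acid response and ATF4 targets, 1 of 19 measured members rose and 5 fell (1 and 9 adjusted over the list alone, camera adjusted p = 1.45e-05, adjusted p = 0.0552 with an estimated correlation). TRIB3 and SLC7A11 changed by -1.66 and -1.69, and SLC7A5 rose by 1.65. In all, 543 genes were higher and 452 lower.

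Lists that moved up with GIP at 8 h in the presence of insulin included oxidative phosphorylation, where 5 of 23 measured members rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 1.62e-09, with 1 array out 2 to 5 passed), with CYCS at 1.23. In ribosome biogenesis, 3 of 19 measured members rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 4.98e-05, with 1 array out 1 to 3 passed). Among mature adipocyte genes, 6 of 20 measured members rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 4.98e-05, adjusted p = 0.0552 with an estimated correlation, with 1 array out 5 to 8 passed), with LPL at 1.81 ± 0.16. Among thermogenic adipocyte genes, 4 of 19 measured members rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.00464, adjusted p = 0.0552 with an estimated correlation). UCP1 rose by 2.43 ± 0.32, PPARGC1A by 1.16 ± 0.17 and ELOVL3 by 1.29 ± 0.22. UCP1 stood at 5.715 ± 0.903 in insulin plus GIP and 3.283 ± 0.178 in insulin, both under the table median, so the size of its rise is uncertain. Among cAMP-responsive genes 6 of 20 measured members rose and 0 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.00406, adjusted p = 0.0712 with an estimated correlation, with 1 array out 3 to 4 passed). Among fatty acid oxidation genes 1 of 19 measured members rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.00464, adjusted p = 0.0581 with an estimated correlation). Among adipose progenitor and fibroblast markers, 1 of 17 measured members rose and 7 fell (1 and 7 adjusted over the list alone, camera adjusted p = 3.54e-05, with 1 array out 3 to 8 passed), with DPP4 at -1.22 ± 0.17 and POSTN at -1.31 ± 0.30. The count of 995 genes became 634 without insulin plus GIP replicate 3 and 541 on the 6 arrays alone.

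At 24 h with insulin present, CA3 rose 11.8-fold (3.56 ± 0.19), CA2 8.91-fold (3.16 ± 0.34) and PRL 7.22-fold (2.85 ± 0.22), and FGL2 and PLA2G2A rose by 1.94 and 1.63. POSTN fell 3.15-fold (-1.66 ± 0.30), and the matrix gene MXRA5, the prostaglandin-degrading enzyme gene HPGD, CENPF and TMEM97 changed by -1.53, -1.43, -1.42 and -1.41. In all, 220 genes were higher and 567 lower. Among adipose progenitor and fibroblast markers, 5 of 17 measured members fell and 0 rose (7 and 1 adjusted over the list alone, camera adjusted p = 0.000338, with 1 array out 2 to 4 passed). Among fatty acid uptake and triglyceride synthesis genes, 5 of 16 measured members rose and 0 fell (8 and 2 adjusted over the list alone, camera adjusted p = 6.36e-05, with 1 array out 1 to 3 passed), with FABP5 at 1.36 ± 0.22. Among glycolysis genes 4 of 19 measured members rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.000338, adjusted p = 0.118 with an estimated correlation). Among oxidative phosphorylation genes 2 of 23 measured members rose and 0 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.000217, adjusted p = 0.118 with an estimated correlation, with 1 array out 0 to 2 passed). Among fatty acid oxidation genes 3 of 19 measured members rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.0159, adjusted p = 0.118 with an estimated correlation, with 1 array out 1 to 2 passed and camera adjusted p = 0.0601 at most). In the amino acid response and ATF4 list 2 of 19 measured members fell and 0 rose (4 and 0 adjusted over the list alone, camera adjusted p = 0.000338, adjusted p = 0.13 with an estimated correlation, with 1 array out 0 to 2 passed). Among cell cycle genes 1 of 20 measured members fell and 0 rose (1 and 0 adjusted over the list alone, camera adjusted p = 0.0142, adjusted p = 0.118 with an estimated correlation, with 1 array out 0 to 2 passed and camera adjusted p = 0.187 at most). Under cyclic loess, 274 genes were higher and 381 lower. The count of 787 became 416 or 461 without insulin plus GIP replicate 1 or 3, 451, 317 or 504 without insulin replicate 1, 2 or 3, and 77 on the 6 arrays alone.

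**Figure D3:**
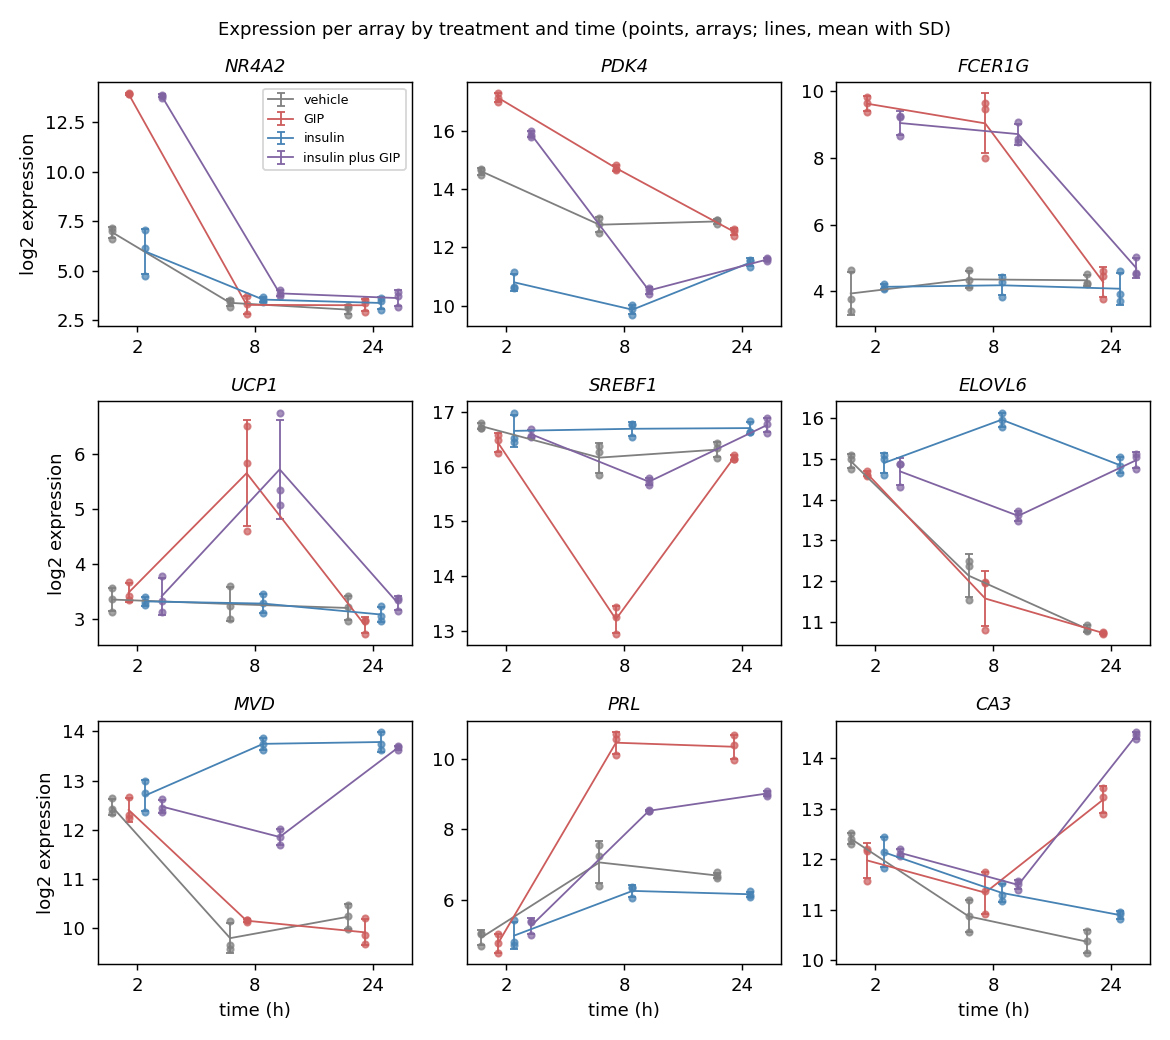
Log2 expression (y axis) of 9 genes at 2, 8 and 24 h (x axis, evenly spaced) in vehicle (grey), GIP (red), insulin (blue) and insulin plus GIP (purple), with a point per array and lines through group means with SD (n = 3). NR4A2 stood at 13.92 and 13.83 in GIP and insulin plus GIP at 2 h against 6.95 in vehicle, and SREBF1 stood at 13.21 in GIP at 8 h against 16.16 in vehicle.

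Both hormones together, compared with vehicle, changed 1493 genes at 2 h, 3394 at 8 h and 2232 at 24 h. At 2 h ADAMTS4, NR4A2 and USP2 rose by 7.10, 6.88 and 6.73, and DEPP1, ZNF217 and KIAA0408 changed by -4.81, -2.91 and -2.60. At 8 h TUBA4A, FCER1G and MLLT11 rose by 5.28, 4.35 and 4.18, and TMEM37, YPEL3 and FBXO32, a ubiquitin ligase of muscle wasting, changed by -3.98, -3.64 and -3.38. At 24 h ELOVL6, CA3 and SLC2A5 rose by 4.14, 4.09 and 3.66, and PLA2G2A, HPGD and FAXDC2 changed by -2.82, -2.79 and -2.43. LEP, the leptin gene, was higher than in vehicle by 1.09 at 24 h, and GIPR by 1.19. In vehicle LEP stood at 13.41 at 2 h and 9.40 at 24 h, and with both hormones at 13.02 and 10.5. For GIPR these levels were 4.85 and 2.88, and 4.56 and 4.08. Both genes thus stood lower at 24 h than at 2 h in vehicle and with both hormones. GIPR stood at 4.08 ± 0.30 against 2.88 ± 0.05 in vehicle, both under the table median, so the size of its rise is uncertain. On the 6 arrays alone, 1263 genes passed at 24 h.

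Whether GIP acted differently with insulin than without it was tested by the difference of the GIP effects (the effect with insulin minus the effect alone). At 2 h DEPP1 had a difference of 2.65 ± 0.26 (adjusted p = 2.32e-07) and PDK4 of 2.56 ± 0.20 (adjusted p = 2.24e-09): GIP raised PDK4 by 2.53 alone and by 5.08 beside insulin, which lowered it. PCK1, SPRY1 and DUSP4 had negative differences of -2.19 ± 0.24, -2.03 ± 0.27 and -1.63 ± 0.20, and NFATC2 had 1.86 ± 0.40 (adjusted p = 0.0491). PCK1 stood at 9.98 in vehicle, 13.49 in GIP, 11.93 in insulin and 13.25 in both. DEPP1 stood at 12.48, 8.53, 8.96 and 7.67 in the same order. Insulin alone moved PCK1 and DEPP1 the same way as GIP, so their differences do not show that insulin reversed the GIP response. At 8 h SREBF1 had 1.99 ± 0.21 (adjusted p = 1.59e-06), as it fell by 2.96 with GIP alone and by 0.97 beside insulin, and RASD1 and NABP1 had 1.36 ± 0.27 and 1.32 ± 0.21. SLCO4C1, ITIH1 and SYN2 had -2.83 ± 0.46, -2.69 ± 0.30 and -2.57 ± 0.31, and PDE3B and PDK4 had -1.05 and -1.29. At 24 h FABP3, PRG4, the joint-lubricant proteoglycan, and TM4SF19-DYNLT2B had -2.23 ± 0.36, -2.10 ± 0.32 and -1.44 ± 0.27 (adjusted p = 0.042). In all, 15 genes had a positive and 13 a negative difference at 2 h, 20 and 52 at 8 h, and 0 and 5 at 24 h, where limma gave 1932 at an unadjusted p under 0.05. The counts of 28, 72 and 5 fell to 17 without GIP 2 h replicate 3 and 18 without insulin 2 h replicate 3, to 46 without insulin plus GIP 8 h replicate 3 and 35 without insulin 8 h replicate 3, to 2 or 3 without any 1 of the 12 arrays at 24 h, and to 7, 16 and 1 on the 12 arrays alone. Other fits called more: 118 and 13 at 8 and 24 h without dim probe sets, and 137 and 52 with a trended robust fit. NFATC2 and TM4SF19-DYNLT2B each lost the call without any 1 of 9 of the 12 arrays (highest adjusted p 0.212 and 0.184), RASD1 without insulin plus GIP 8 h replicate 3, insulin 8 h replicate 3 or vehicle 8 h replicate 1 (highest 0.0753), and on the 12 arrays alone NFATC2, RASD1, NABP1, PRG4 and TM4SF19-DYNLT2B did not pass. TM4SF19-DYNLT2B also lost the call with the replicate number as a block (adjusted p = 0.0617) or as a block within each time (adjusted p = 0.0947).

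Across genes, which are not independent replicates, the log2 changes of GIP with insulin and without it had a Pearson r of 0.697 at 2 h, 0.529 at 8 h and 0.230 at 24 h. Spearman's rho was 0.360, 0.360 and 0.170, and Pearson's r without dim probe sets was 0.814, 0.668 and 0.361. These pairs of comparisons share no arrays. Genes called in the same direction in both numbered 662, 570 and 82 at the 3 times, against 34.1, 39.0 and 3.07 for independent lists of those sizes. Genes called in opposite directions numbered 2, 4 and 1, against 35.2, 38.4 and 3.20. CA3, CA2, PRL and FGL2 were among the genes higher in both at 24 h.

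**Figure D4:**
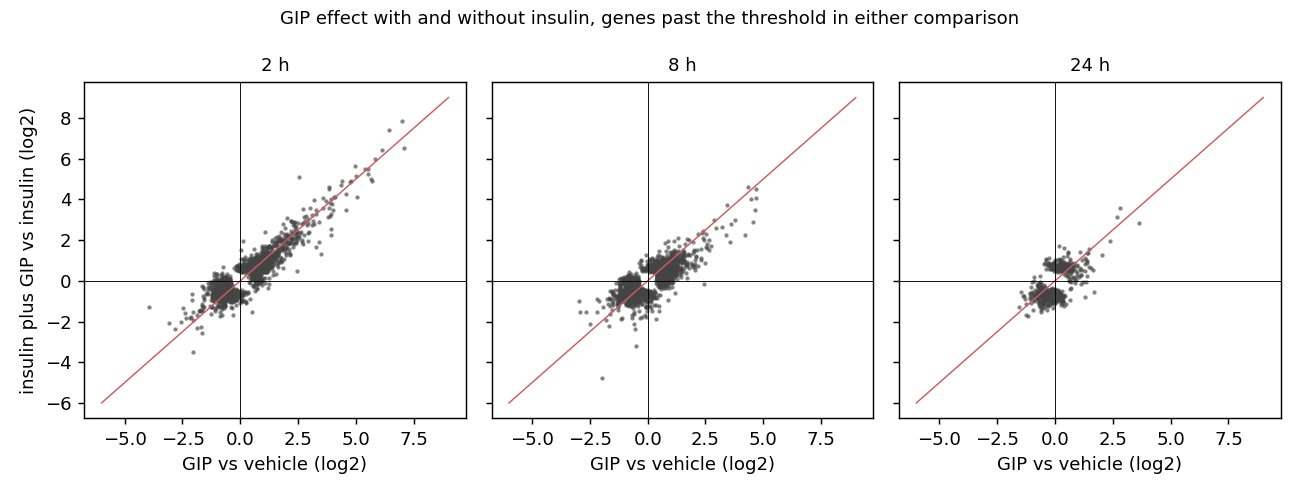
Log2 change by GIP without insulin (x axis) and with insulin (y axis) for genes with a symbol past the threshold in either comparison at 2, 8 and 24 h, a point per gene, with the line of equal effects in red. Of the 1807, 2083 and 874 probe sets called in either comparison, 91.5%, 89.2% and 77.3% had the same sign in both.

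GIP alone and insulin alone called 145 genes in the same direction at 2 h, 422 at 8 h and 50 at 24 h, against 10.6, 67.8 and 5.03 for independent lists of those sizes. DEPP1 fell with both hormones at 2 h and PCK1 rose with both. Genes called in opposite directions numbered 34, 99 and 15, against 11.0, 66.1 and 4.94, and PDK4 was among them at 2 and 8 h, rising with GIP and falling with insulin. LIPE and PLIN1 rose with GIP and fell with insulin at 8 h. The call of PLIN1 with GIP, 0.56 ± 0.16 (adjusted p = 0.023), ended without GIP 8 h replicate 1 or vehicle 8 h replicate 1 or 2, with adjusted p from 0.0134 to 0.189 over the 6 arrays left out in turn. Both comparisons use the same vehicle arrays, and 100 simulations of unchanged groups against such shared controls gave at most 0 shared genes in either direction. Unchanged groups call almost no genes, so this value is no reference for lists that hold real effects, and the independent lists leave out the shared controls. With 3 vehicle arrays per time the controls were not split, and part of the excess over independent lists may come from the shared controls.

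The effects were then compared between times by the difference of the 24 h and 2 h effects. For GIP, ADAMTS4, NR4A2 and ZNF331 had differences of -7.51 ± 0.26, -6.76 ± 0.44 and -6.59 ± 0.35, and DEPP1, PRL and DUSP6 had 4.52 ± 0.26, 3.82 ± 0.31 and 3.33 ± 0.24, with 349 positive and 487 negative differences in all. For insulin, ELOVL6, FABP3 and SLC2A5 had 4.07 ± 0.33, 3.95 ± 0.36 and 3.47 ± 0.31, and PLA2G2A, LONRF3 and GPX3 had -4.42 ± 0.36, -2.04 ± 0.41 and -2.02 ± 0.38, with 238 positive and 174 negative, or 243 in all on the 12 arrays alone and 638 without dim probe sets. The vehicle cells also changed with time. From 2 h to 24 h in vehicle, NR4A1 fell 189-fold (-7.56 ± 0.20), EGR1 46.0-fold (-5.53 ± 0.22) and ID1 40.8-fold (-5.35 ± 0.24), while PLA2G2A, MMP1 and TMEM37 rose by 3.98, 2.63 and 2.04. LEP fell 16.0-fold. In all, 510 genes were higher and 923 lower at 24 h, or 917 in all on the 6 arrays alone and 799 with the replicate number as a block within each time.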

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

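The patterns weighed here were picked after the main results were seen, and the tests of their explanations were written down before those tests were run. The first results listed are differences between groups that passed the test of the difference itself. The GIP effect differed with insulin present for 28 genes at 2 h, 72 at 8 h and 5 at 24 h. At 2 h the differences, on the log2 scale, were 2.65 for DEPP1, 2.56 for PDK4, 1.86 for NFATC2, -2.19 for PCK1, -2.03 for SPRY1 and -1.63 for DUSP4. At 8 h they were 1.99 for SREBF1, 1.36 for RASD1, 1.32 for NABP1, -2.83 for SLCO4C1, -2.69 for ITIH1 and -2.57 for SYN2. At 24 h they were -2.23 for FABP3, -2.10 for PRG4 and -1.44 for TM4SF19-DYNLT2B.

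The GIP effect differed between 24 h and 2 h for 836 genes, with 4.52 for DEPP1, 3.82 for PRL, 3.33 for DUSP6, -7.51 for ADAMTS4, -6.76 for NR4A2 and -6.59 for ZNF331. The insulin effect differed for 412 genes, with 4.07 for ELOVL6, 3.95 for FABP3, 3.47 for SLC2A5, -4.42 for PLA2G2A, -2.04 for LONRF3 and -2.02 for GPX3.

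For these 5 counts, 100 splits of the 12 arrays into 4 groups of 3 were drawn, the real one included. As many genes were called in 14 splits for the interaction at 2 h (28 genes, highest other split 704), 20 at 8 h (72, highest other 1175) and 15 at 24 h (5, highest other 740). For the 24 h minus 2 h differences the numbers were 8 for GIP (836, highest other 1773) and 7 for insulin (412, highest other 698). Splits that call several times the real count point to a structure of the samples: such a split moves treated arrays or times across the contrast, so the effect of GIP, of insulin or of time itself enters the difference. These splits therefore do not tell whether chance is excluded, and the differences rest on the adjusted p of each gene.

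Comparisons of 3 arrays with 3 have 10 splits, too few for a share under 0.05, so only the real and the highest other counts are given. At 2, 8 and 24 h they were 1452, 1662 and 170 genes against at most 0, 1 and 0 in another split for GIP vs vehicle and 317, 1722 and 1253 genes against at most 1, 1 and 0 in another split for insulin vs vehicle. They were 1493, 3394 and 2232 genes against at most 0, 1 and 2 in another split for insulin plus GIP vs vehicle and 1019, 995 and 787 genes against at most 0, 1 and 0 in another split for insulin plus GIP vs insulin, and 1433 against 0 for vehicle at 24 h against 2 h. In each of these, 1 of the 10 splits, the real one, called as many genes. For gene lists the real counts and the highest of the other splits at the 3 times were 6, 10 and 11 against 5, 9 and 2 for GIP vs vehicle, 10, 11 and 11 against 10, 8 and 8 for insulin vs vehicle, and 6, 10 and 7 against 7, 9 and 4 for insulin plus GIP vs insulin. As many lists were called in 2 of 10 splits for insulin vs vehicle at 2 h and for insulin plus GIP vs insulin at 2 h, and in 1 of 10 in the other 7 comparisons. Every other split puts arrays of both real groups on each side. Part of the real effect then stays in the difference and part enters the spread. The counts of the other splits, of genes or lists, are therefore no measure of chance.

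FCER1G, a gene of immune cells, rose by 5.69 with GIP at 2 h, and CD14 by 1.09. Macrophage RNA in the GIP cultures would raise the other macrophage markers too, but the median change of the 13 others was 0.153 (95% interval of the median -0.124 to 0.345), and TYROBP stood at 7.18 against 6.76 in vehicle. That interval is taken over the 13 markers, so it measures the spread among them and not between arrays. Cyclic loess, run on the values as deposited, left the FCER1G change at 5.73, so the change did not depend on this further scaling. It cannot undo the normalization already applied, so this value does not decide whether that normalization was the cause. A response of the adipocytes themselves to GIP remains a hypothesis, and how the probe set hybridises was not tested.

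At 24 h GIP called 170 genes without insulin and 787 with it. Noisier arrays without insulin were weighed as a reason for the fewer calls. The within-group SD there was 0.978 times that with insulin (0.944 to 1.00 with each of the 12 arrays left out in turn). The arrays without insulin were thus not noisier by this measure. However, the fit used a spread per gene shared by all groups, so such noise would widen the SE of both comparisons alike. The ratio of SDs therefore does not tell why fewer genes were called without insulin. The variance of log2 changes beyond within-group error with insulin was 2.31 times that without (0.0464 against 0.0201), and 1.83 to 3.05 times with an array left out, but with alike noise this restates the difference in calls and decides nothing. A wider late response to GIP beside insulin, a treatment of the design, stays open as an untested hypothesis. The test of the difference gene by gene passed for 5 genes at 24 h, but for 13 without dim probe sets and 52 with a trended robust fit, so their number is not firm.

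POSTN, TAGLN and ACTA2, genes of matrix and contractile cells, fell with GIP at 24 h by 1.25, 0.78 and 1.07 on the log2 scale, the POSTN call resting on 5 of the 6 arrays as given in the report. If fibroblast-like cells alone carried these transcripts, a lower share of them would lower the other 15 progenitor and fibroblast markers to a like extent. Their median change was smaller, -0.168 (95% interval of the median -0.384 to 0.0331, taken over the markers and not over arrays). VIM, among them, stood at 17.00 against 17.38 in vehicle. As a list the markers, POSTN and TAGLN included, moved down (camera adjusted p = 1.73e-06). Whether the adipocytes carry these transcripts too was not tested, so these values do not decide whether the share of such cells fell. Cyclic loess on the values as deposited left POSTN at -1.23, so this further scaling hardly changed it. The normalization already applied cannot be undone in this way, so it was not tested as a cause. A change of matrix and contractile genes within the cells stays open as a hypothesis, as does a change of the cell mixture.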

How the results depend on the processing

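All alternatives in this part were chosen before any value was seen, but the counts of list members with an array left out were added after the results were known. The 18 counts of called genes stayed within 1.5 times under median centring, the 1.5-fold minimum and 1 row per gene. No result of a single gene that was called in the main fit or in the alternative reversed its sign. Results called in neither were not compared by sign. For the other alternatives the counts that moved by more are these, and the cause was not tested except where stated. Cyclic loess called 3 genes for the interaction at 24 h against 5. Leaving out dim rows, which tests fewer rows, called 285 for GIP at 24 h, 118 and 13 for the interaction at 8 and 24 h and 638 for the insulin effect at 24 h minus 2 h. The trended robust fit called 287 for GIP at 24 h and 137 and 52 for the interaction at 8 and 24 h, array weights called 257 for GIP at 24 h, and plain ANOVA after adjustment called 12 for the interaction at 24 h. Plain ANOVA after adjustment also ended the call of NFATC2 in the interaction at 2 h (adjusted p = 0.126).

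The submitters' rule of an unadjusted p with 1.5-fold, which corrects for no multiple testing, called 495 genes for GIP at 24 h, 759 for insulin at 2 h, 1025, 1117 and 1223 for the interactions at 2, 8 and 24 h, 2344 for the GIP and 1686 for the insulin effect at 24 h minus 2 h. Fits on only the groups compared, with fewer arrays to estimate the spread, called 795, 780 and 39 for GIP, 127, 906 and 674 for insulin, and 636, 541 and 77 for insulin plus GIP vs insulin at 2, 8 and 24 h. They called 1263 for insulin plus GIP vs vehicle at 24 h, 7, 16 and 1 for the interactions, 243 for the insulin effect at 24 h minus 2 h, and 917 for vehicle at 24 h against 2 h.

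The replicate numbers do not pair the samples: of 198 pairs of arrays with the same number in different groups, 13 had deviations correlated above 0.1 (mean 0.00305, against -0.00149 for different numbers), and 16 of 36 arrays correlated best with their own number. With the replicate block, 2 genes were called for the interaction at 24 h, likewise 2 with the replicate block within time, which called 799 for vehicle at 24 h against 2 h. The other counts stayed within 1.5 times with either block.

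Leaving out each array in turn leaves 2 arrays in that group, assumed to vary like the others. The counts ranged from 1073 to 1275, 1138 to 1580 and 93 to 126 for GIP at 2, 8 and 24 h, 204 to 244, 1295 to 1404 and 849 to 980 for insulin. They ranged from 782 to 852, 634 to 776 and 317 to 579 for insulin plus GIP vs insulin, and 17 to 28, 35 to 61 and 2 to 3 for the interactions. For GIP lists at 24 h they ranged from 7 to 12. The Pearson r of the GIP effects with and without insulin ranged from 0.659 to 0.689 at 2 h and 0.486 to 0.523 at 8 h, and from 0.183 to 0.258 at 24 h. It was 0.814, 0.668 and 0.361 at the 3 times without dim rows, 0.905, 0.779 and 0.599 over called genes, and 0.360, 0.360 and 0.170 by Spearman's rho. Without dim rows, GIP and insulin shared 108 genes in the same and 31 in opposite directions at 24 h, and 153 in opposite directions at 8 h.

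For gene lists, camera with an estimated correlation called 1, 7 and 6 lists for GIP and 1, 5 and 2 for insulin plus GIP vs insulin at 2, 8 and 24 h. Fry, which tests whether a list's genes move one way on balance and not against other genes, called 12 and 19 lists for GIP at 2 and 8 h and 13 for insulin plus GIP vs insulin at 2 h. Of 1096 results of single genes per setting, cyclic loess ended 17 calls and added 16, and fits on only the groups compared ended 164. Signal over background was not used, which limits what can be said of low levels.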

Other observations

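Some of the lists fixed beforehand have not been described above. Among interferon-stimulated genes at 8 h of GIP, 2 of 19 measured members rose and 3 fell (2 and 5 adjusted over the list alone, camera adjusted p = 0.885, with 1 array out 2 to 5 passed): OAS1 and OASL rose 18.6-fold and 12.1-fold, the latter from a vehicle mean of 4.52 not shown to be above background. They rose by 2.23 and 2.78 beside insulin, while RIGI, a sensor of viral RNA, changed by -1.06 beside insulin. The list's median at 8 h of GIP was below 0 and its mean above. At 2 h of insulin, 0 of 19 measured members passed the test (0 adjusted over the list alone, camera adjusted p = 0.00211, with 1 array out camera adjusted p = 0.111 at most). Among circadian clock genes at 24 h of GIP, 2 of 16 measured members rose and 0 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.00195, with 1 array out 1 to 2 passed). At 2 h of insulin 1 of 16 measured members rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.00416, with 1 array out 1 to 2 passed). BHLHE40 stayed higher with insulin, at 1.93 ± 0.14, 1.95 ± 0.14 and 1.93 ± 0.14 at the 3 times, and NPAS2 was higher at 8 and 24 h by 1.29 and 1.31. NFIL3 and CRY2 rose by 2.24 and 2.00 with GIP at 2 h, when 2 of 16 measured members rose and 3 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.652, with 1 array out 3 to 5 passed).

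Among unfolded protein response genes at 8 h of insulin, 3 of 15 measured members rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.000642), with the chaperone genes HSPA5 and HYOU1 at 0.91 ± 0.10 and 1.08 ± 0.18. At 24 h 0 of 15 measured members passed the test (0 adjusted over the list alone, camera adjusted p = 0.0424, with 1 array out camera adjusted p = 0.0929 at most). XBP1 rose by 1.07 with GIP at 2 h, when 3 of 15 measured members rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.23). Camera called the endothelial markers in none of the 9 comparisons, while fry, a test of the list by itself, had an adjusted p of 0.044 for insulin at 8 h and 0.0199 for insulin plus GIP vs insulin at 24 h. At 8 h of GIP 1 of 11 measured members rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.863, with 1 array out 0 to 1 passed). KCNJ8, in the mural and smooth muscle list, rose by 1.79 with GIP and fell by 1.05 with insulin at 2 h. PCNA, in the cell cycle list, rose by 1.24 with GIP at 2 h, and AURKA by 1.06 with GIP beside insulin.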
